A study of Homo sapiens with 6 samples.

How the data were processed

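The series measured total RNA from SiHa cells on 6 Affymetrix arrays with biotin labelling, per the labels' protocols. The labels put 3 arrays in a group with a negative-control guide RNA and 3 in a group with a CRISPR-Cas9 knockout of KCP, and both groups' labels mention drug treatment. The labels number the arrays of each group 1 to 3 but do not say that they came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

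The deposited table held log2 expression values per probe set, made by the authors with robust multi-array average (RMA) per the submitters' processing notes. RMA corrects background, quantile-normalizes the arrays against one another and summarises each probe set's probes by median polish. The software, its version and any filter are not given in the sources used here. The sorted values of any pair of arrays differed by at most 0.091, as values normalized between arrays do. RMA compresses differences of dim probe sets, and quantile normalization removes any shift shared by most genes. No detection calls were used, so no probe set could be called absent and no bound from background was set. For arrays of this kind their number, 3 per group, limits the precision.

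The table held 49395 probe sets, of which 102 were controls. The platform annotation, of 2021, gave 44988 probe sets a single gene symbol and 1832 several symbols. It did not list another 2473, which are unnamed here. The identifiers of 44961 of the singly named probe sets were found in a gene table of assembly GRCh38.p14, and 0 symbols needed updating. That table was used only for names, chromosomes and the order of genes, since the sources name no genome build, and no coordinates are given.

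Each gene was represented by the probe set with the highest mean over all 6 arrays among probe sets with a single symbol, which gave 18132 genes, 6398 of them with 1 probe set. Differences are knockout minus control on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, two-sided. Every adjusted p for a gene or probe set comes from limma. All 49293 non-control probe sets were also tested one by one. Errors after ± are SDs over the 3 arrays of a group unless SE is stated.

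The genes named are KCP, the 4 regulators named in the series description (SPI1, CCND1, PML and CEBPA), the 10 largest increases and the 10 largest decreases among genes past the threshold whose groups did not overlap, and from each gene list up to 3 members past the threshold, or the member with the smallest p where none passed. This rule, the tests, the alternatives and 27 gene lists were fixed before the data were examined. Of 534 genes in the lists, 483 were measured. Lists were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists, and again with a correlation estimated from the data. The limma function fry, which asks whether a list's genes move on balance in a single direction or in either direction, was run as well. Counts of list members past the threshold use the adjustment over all genes, and counts adjusted over the list alone are given beside them.

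The alternatives were a further quantile normalization, centring each array on its median, leaving out the dimmest 40% or 20% of probe sets, an intensity trend with robust moderation, array weights, the replicate number as a block, leaving out each array in turn, 3 other ways to choose a gene's probe set, and other fold and p thresholds. Leaving out probe sets whose names end in _s_at or _x_at, which can bind several transcripts, and using the other KCP probe set were added after the data were seen. The fit was tested on simulated log2 values with the spread of these arrays for the 18132 genes. With 200 genes changed, it recovered 32.9% of genes changed by 0.3, 70.2% of those changed by 0.6 and 95.9% of those changed by 1 on the log2 scale, and 3.62% of the genes called were false. With no gene changed it called 0 genes. The noise was drawn independently for each gene, in a single run per setting, so these values do not cover shifts that genes share on an array. Figures were drawn with matplotlib 3.10.9.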

Results

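Gene expression was profiled in SiHa cells, a line derived from a human cervical squamous carcinoma that carries papillomavirus. In 3 of the 6 arrays the cells had received a negative-control guide RNA. In the other 3 the gene KCP had been targeted with CRISPR-Cas9, an RNA-guided nuclease, after treatment with paclitaxel, a drug that stabilises microtubules and blocks mitosis. The labels call the control cells drug-treated without naming the drug, and no untreated cells were analysed here. The labels also do not say whether the knockout cells were a clone or a pool, or whether the drug was present at harvest. The comparison is therefore between these 2 cell populations, which may differ in more than KCP, in a study of how KCP bears on paclitaxel resistance. KCP encodes a secreted, chordin-like protein that modulates bone morphogenetic protein (BMP) signalling. Median log2 signal was 5.83 to 5.85 on every array. Arrays correlated at 0.9972 to 0.9985 within groups and at 0.9967 to 0.9973 between groups (Pearson's r across probe sets, which are not independent replicates). The first principal component of the genes, with 38.2% of the variance, separated the groups, with control arrays at −10.6 to −7.11 and knockout arrays at 7.81 to 10.4. Control replicate 3 stood apart on the second component (24.5% of the variance), at −14.4 against −2.92 to 7.47 for the other arrays.

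The KCP signal did not differ detectably between the groups. The brighter of its probe sets, 11741713_at, read 5.24 ± 0.22 in control and 5.22 ± 0.14 in knockout arrays (n = 3 each), a log2 difference of −0.025 (95% confidence interval −0.30 to 0.25, limma adjusted p = 0.939). The dimmer one, 11734493_at, read 4.53 ± 0.14 and 4.64 ± 0.16, a difference of 0.10 (adjusted p = 0.652). KCP lies on chromosome 7. The sources used here do not say where its probes sit relative to the edited site, and an edit that disrupts the protein need not lower the transcript, so these values check the labels in neither direction.

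The series description names SPI1, CCND1, PML and CEBPA from an upstream-regulator inference in which SPI1 was activated, CCND1 inhibited, and PML and CEBPA activated. Of these, the transcript of CCND1, which encodes the G1-phase cyclin D1, fell 1.41-fold, from 6.65 ± 0.13 to 6.15 ± 0.05 (n = 3 each; log2 difference −0.50, SE 0.07, adjusted p = 0.0165). All 4 CCND1 probe sets were lower, by −0.52 to −0.35, and 2 of them passed the threshold one by one. CEBPA, which encodes a differentiation-promoting transcription factor, rose 1.36-fold, from 5.78 ± 0.09 to 6.22 ± 0.13 (log2 difference 0.45, SE 0.08, adjusted p = 0.0326). The only CEBPA probe set, 11726294_s_at, is of a kind that can bind several transcripts. Transcripts of SPI1, a myeloid transcription factor, read 4.37 ± 0.07 and 4.33 ± 0.07 (difference −0.039, adjusted p = 0.792). The SPI1 probe set lies at percentile 32.5 of all probe sets, and without detection calls it stays open whether it was above background. The inference concerns a factor's activity, which its own transcript does not measure. The 10 probe sets of PML, which encodes the scaffold of PML nuclear bodies, disagreed. The brightest gave −0.057 (adjusted p = 0.697), the set ranged from −0.10 to 0.46, and 1 of them, 11726876_a_at, was past the threshold at 0.46 (adjusted p = 0.0227). With 1 array left out at a time, CCND1 stayed past the threshold in 2 of 6 runs (without control replicate 2 or 3; difference −0.57 to −0.44, adjusted p 0.0334 to 0.0828 over the 6). CEBPA did so in 0 of 6, with differences of 0.40 to 0.52 (adjusted p 0.0553 to 0.122).

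**Figure D1:**
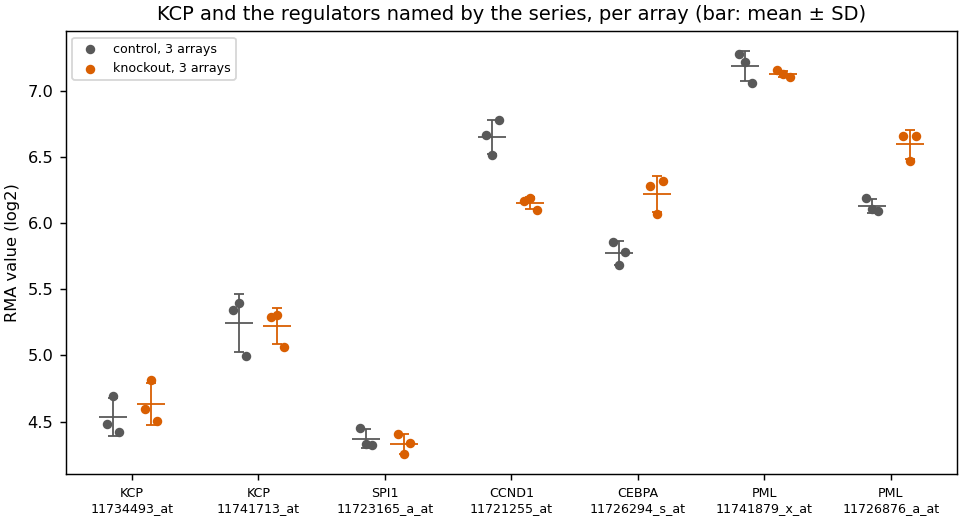
RMA values (log2) of single arrays for both KCP probe sets, SPI1, CCND1, CEBPA, and the brightest and the most changed PML probe set; points are arrays, horizontal bars are means of 3 arrays and whiskers are SDs. Knockout arrays overlap control arrays for KCP and SPI1, lie below them for CCND1, and lie above them for CEBPA and for 1 of the PML probe sets.

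Across all genes, the largest increase was that of LCN2, an iron-scavenging lipocalin, and the largest decrease that of SERPINB4, a protease inhibitor. LCN2 rose 2.43-fold (log2 difference 1.28, SE 0.06, adjusted p = 0.000626). CLGN, a testis chaperone of the endoplasmic reticulum, rose 2.32-fold with all 5 of its probe sets past the threshold, and SMC1B, a meiotic cohesin subunit, rose 2.12-fold. LAMP3 (2.21-fold), OASL (2.05-fold) and DDX60 (1.84-fold) are known interferon-inducible genes. The stress-inducible chaperone gene HSPA6 rose 1.94-fold, the stress-responsive NIBAN1 1.84-fold, the aldo-keto reductase gene AKR1C2 1.79-fold and the zinc-finger repressor gene ZBTB20 1.94-fold, the last with 1 of its 2 probe sets past the threshold.

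The paralogs SERPINB4 and SERPINB3, which encode the squamous cell carcinoma antigens, fell 2.38-fold (log2 difference −1.25, SE 0.07, adjusted p = 0.00108) and 2.31-fold (−1.21, SE 0.08, adjusted p = 0.00156). Their sequences are close, and the SERPINB4 probe set is of a kind that can bind both, so they are not treated as separate measurements. The gap-junction gene GJB2 fell 1.91-fold, the fibrinogen chain gene FGG 1.75-fold (1 of 2 probe sets past the threshold, the other at −0.21), the transglutaminase gene TGM2 1.69-fold, the calprotectin subunit gene S100A8 1.64-fold and the carbonic anhydrase gene CA12 1.64-fold. SAA1, an acute-phase protein gene, fell 1.60-fold, HLA-DQB1, an MHC class II gene with 2 of 8 probe sets past the threshold, fell 1.60-fold, and the carboxypeptidase gene CPA4 fell 1.60-fold. The probe sets used for OASL, NIBAN1, GJB2, FGG, TGM2, SAA1 and HLA-DQB1 are also of a kind that can bind several transcripts. The FGG signal was dim, at 4.59 ± 0.04 in control and 3.78 ± 0.10 in knockout arrays. Without detection calls it stays open whether FGG was above background. All 20 genes had groups that did not overlap, as the rule for naming them required. Of the 49 named genes past the threshold, 31 had several probe sets, and one by one every probe set passed for 11 of these, some for 19 and none for 1 (PLK1). For CA12, HLA-DQB1, ABCC3 and CDC20 a probe set had the other sign.

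In all, 650 of 18132 genes passed the threshold, 414 higher and 236 lower, with a median change of 1.27-fold. At least 1.5-fold were 45 of them (31 higher, 14 lower), and at least 2-fold 7 (5 higher, 2 lower). An unadjusted p under 0.05 was reached by 3557 genes, and the groups did not overlap in 27.2% of genes, against 10% by chance. Of the 49293 probe sets, 1141 passed, 667 higher and 474 lower. The series description gives 491 genes without stating its threshold. With 1 array left out, the count was 65, 79 and 120 without knockout replicate 2, 3 and 1, and 132, 200 and 537 without control replicate 2, 1 and 3. As a sign of RNA integrity, 5′ minus 3′ signal of the arrays' actin control probe sets was compared, and it was lower in knockout (−0.79 ± 0.01) than in control arrays (−0.60 ± 0.06; n = 3 each, difference −0.19, two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). For GAPDH the difference was 0.013 (exact p = 0.7). HUMISGF3A went in the direction of actin, rising by 0.079 at its 5′ and 0.28 at its 3′ probe set. M27830 rose by 0.22 and 0.022, and HUMRGE by 0.18 and 0.20, in that order. Neither M27830 nor HUMRGE is read as a sign of messenger RNA integrity. The 3′ probe set of M27830 was dim (4.83 in control arrays, against 12.6 for its 5′ probe set). Spiked-in control transcripts read higher in the knockout arrays, with 23 of 24 labelling probe sets (median difference 0.15) and 18 of 18 hybridisation probe sets (0.082) positive and 0 past the threshold. Several probe sets read each such transcript, and the median per array differed by 0.12 and 0.10 (two-sided exact permutation p = 0.1 for both, the smallest possible).

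**Figure D2:**
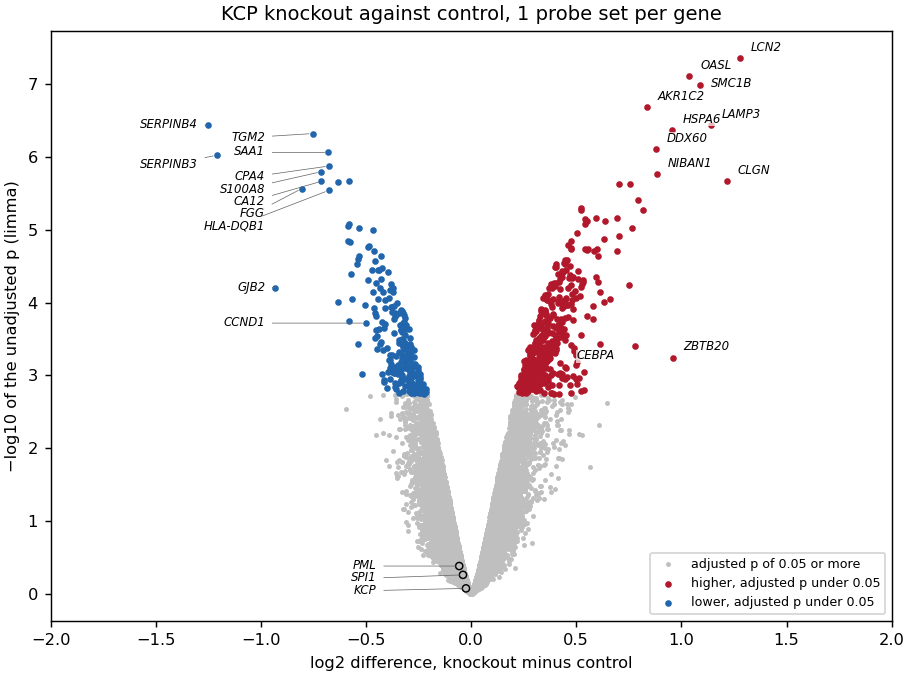
Log2 difference (knockout minus control, horizontal) against −log10 of the unadjusted limma p (vertical) for 18132 genes, 1 point each, with the 20 genes of largest change and the 5 genes named by the series labelled. Red points are the 414 genes higher and blue points the 236 genes lower at an adjusted p under 0.05, and open circles mark KCP, SPI1 and PML, which did not pass.

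Hypoxia-inducible and glycolytic genes and mitotic genes were lower in the knockout arrays, and interferon-stimulated genes were higher. Of 17 measured genes of the hypoxia and glycolysis list, 8 fell and 0 rose (0 higher and 11 lower adjusted over the list alone), and all 17 differences were negative, with a median of −0.25. EGLN3, an oxygen-sensing prolyl hydroxylase gene with 1 of 3 probe sets past the threshold, fell 1.37-fold, ANKRD37 1.31-fold (1 of 2) and NDRG1, a stress gene with all 6 probe sets past the threshold, 1.27-fold. The list was past the threshold in camera (adjusted p = 4.57e-11; adjusted p = 0.0378 with an estimated correlation). Of 24 genes of mitosis and the spindle checkpoint, 11 fell and 0 rose (17 lower adjusted over the list alone), with a median of −0.22. They included the mitotic kinesin gene KIF20A (1.38-fold), the anaphase activator gene CDC20 (1.33-fold, with 2 of 3 probe sets past the threshold) and the mitotic kinase gene PLK1 (1.29-fold, adjusted p = 0.0442, with 0 of 3 probe sets past the threshold one by one and all 3 lower). That list too was past the threshold (adjusted p = 4.57e-11; adjusted p = 0.0378 with an estimated correlation).

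Of 32 interferon-stimulated genes, 11 rose, led by OASL (1.04), IFIT1 (0.59) and IFIT2 (0.56), which encode antiviral effectors, and 1 fell, the antiviral tether gene BST2 (−0.33), named after its value was seen. Adjusted over the list alone, 15 were higher and 1 lower. The median was 0.19 (camera adjusted p = 1.91e-10; adjusted p = 0.0378 with an estimated correlation).

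For 3 more lists the call was lost once the correlation was estimated. Of 16 antioxidant target genes of NRF2, 3 rose and 0 fell (4 higher and 1 lower adjusted over the list alone; median 0.092, camera adjusted p = 0.000916; adjusted p = 0.101 with an estimated correlation). The 3 were AKR1C2, AKR1C1 (1.63-fold) and AKR1C3 (1.34-fold), near-identical steroid-reducing enzymes whose probes were not shown to tell them apart. Of 19 ribosomal protein genes, only RPL13 passed (1.18-fold higher; 1 adjusted over the list alone), while all 19 differences were positive with a median of 0.068 (adjusted p = 0.00207; adjusted p = 0.118 with an estimated correlation). That median was −0.012 without probe sets that can bind several transcripts. Of the 10 measured neighbours of KCP on chromosome 7, 0 passed over all genes and 1, TNPO3, a nuclear import receptor gene, adjusted over the list alone (−0.20, adjusted p over all genes = 0.081). Their median was −0.14 (adjusted p = 0.0263; adjusted p = 0.315 with an estimated correlation), and the call ended without control replicate 1 (adjusted p = 0.0779), control replicate 3 (0.064) or knockout replicate 1 (0.0757).

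**Figure D3:**
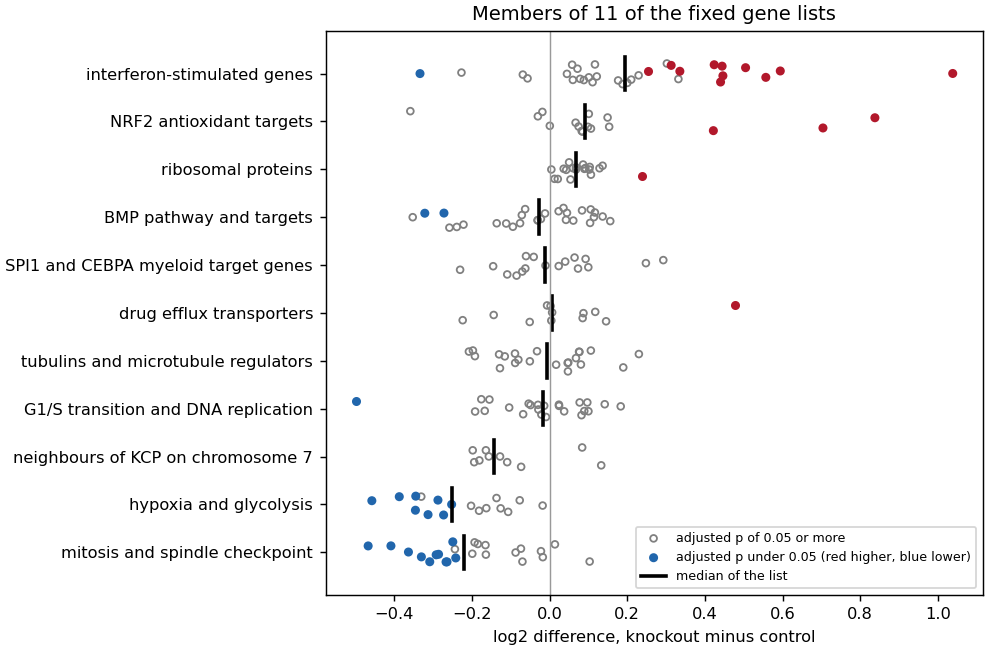
Log2 difference (knockout minus control) of every measured member of 11 of the 27 gene lists, 1 point per gene, with filled points for adjusted p under 0.05 (red higher, blue lower) and a black bar at each list's median. The medians of the mitosis (−0.22) and hypoxia (−0.25) lists lie left of 0 and that of the interferon-stimulated genes (0.19) to the right, while those of the tubulin (−0.0078) and drug efflux (0.0054) lists lie near 0.

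The drug efflux, microtubule, G1/S, p53 and apoptosis lists did not pass camera. Among 12 drug efflux transporters, 1 rose, also adjusted over the list alone: ABCC3, a transporter of organic anions (0.48, adjusted p = 0.0125), whose other probe set gave −0.15. The list's median was 0.0054 (camera adjusted p = 0.521). Of 22 tubulins and microtubule regulators, 0 passed by either adjustment, and TUBA1A had the smallest p (0.19, adjusted p = 0.0808; list adjusted p = 0.53). In the 24 genes of the G1/S transition and DNA replication, only CCND1 passed, also adjusted over the list alone (list median −0.018, adjusted p = 0.521). Among 18 cell cycle inhibitors and p53 targets, 0 passed over all genes and 3 higher and 2 lower adjusted over the list alone, with GDF15 at 0.28 (adjusted p = 0.0785; list adjusted p = 0.668). None of 18 apoptosis promoters passed by either adjustment (BAX −0.25, adjusted p = 0.0779; list adjusted p = 0.189), nor did any of 11 apoptosis inhibitors (CFLAR −0.27, adjusted p = 0.0964; list median −0.058, adjusted p = 0.159). The inhibitor list did pass with the most variable probe set per gene (median −0.17, adjusted p = 0.011) and without probe sets that can bind several transcripts (−0.12, adjusted p = 0.0152), so its result depends on the probe sets used.

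In the BMP pathway, on which KCP acts, ID3 (−0.32) and ID1 (−0.27), both classical BMP target genes, fell, and 26 of 28 members did not pass (4 lower adjusted over the list alone). The list's median was −0.026 (adjusted p = 0.19), and it passed without the dimmest 40% of probe sets (−0.072, adjusted p = 0.0393; adjusted p 0.0393 to 0.544 over 18 alternatives). Of 21 TGF-beta pathway genes, ANGPTL4 (−0.43), also a hypoxia-inducible gene, and PMEPA1 (−0.37), a feedback inhibitor, fell (1 higher and 5 lower adjusted over the list alone; list median −0.069, adjusted p = 0.138). That list too passed without the dimmest 40% (−0.075, adjusted p = 0.038). The 17 myeloid target genes of SPI1 and CEBPA held 0 past the threshold over all genes and 1 higher and 1 lower adjusted over the list alone, with CD68, a macrophage lysosomal marker, at 0.29 (adjusted p = 0.0701). Their median was −0.011 and their mean 0.0070, and the list adjusted p was 0.934.

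The remaining lists did not pass camera either. In squamous differentiation, the calprotectin genes S100A8 (−0.71) and S100A9 (−0.42) fell and the cornified envelope gene CSTA (0.40) rose among 20 members, with the same counts adjusted over the list alone (list adjusted p = 0.189). Of 19 mesenchymal genes, LOX (−0.38), a collagen cross-linking enzyme gene, and S100A4 (−0.32) fell and the receptor kinase gene AXL (0.33) rose (2 higher and 3 lower adjusted over the list alone; list adjusted p = 0.53). Of 18 epithelial junction genes 0 passed by either adjustment (OCLN 0.19, adjusted p = 0.164; list adjusted p = 0.53). Of 21 NF-kB target and cytokine genes, 3 fell, with the chemokine genes CCL2 (−0.40) and CCL20 (−0.34) largest and IL1B (−0.31), named after its value was seen, the other, and CXCL2 rose (0.32; 4 higher and 6 lower adjusted over the list alone; list adjusted p = 0.512). RAD54L, a recombination gene, fell (−0.36) among 15 DNA repair genes, and it was the only one adjusted over the list alone (list adjusted p = 0.383). EGR1, an immediate-early gene, rose (0.30) among 22 MAPK feedback genes, again the only one adjusted over the list alone (list adjusted p = 0.53). HSPB1, a small chaperone gene, fell (−0.32) among 12 heat shock genes (2 higher and 2 lower adjusted over the list alone; list adjusted p = 0.383).

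No member passed over all genes in 5 further lists. These were 20 genes of the unfolded protein response (3 lower adjusted over the list alone; DNAJB9 −0.30, adjusted p = 0.0687; list adjusted p = 0.159), 12 of cholesterol synthesis (1 lower adjusted over the list alone; MVD −0.20, adjusted p = 0.0571; list adjusted p = 0.292) and 19 of oxidative phosphorylation (0 adjusted over the list alone; ATP5F1B −0.13, adjusted p = 0.161; list adjusted p = 0.292). The markers of other cell types, 10 fibroblast genes (1 higher adjusted over the list alone; COL1A1 0.22, adjusted p = 0.055; list adjusted p = 0.51) and 9 lymphoid and endothelial genes (0 adjusted over the list alone; VWF −0.16, adjusted p = 0.489; list adjusted p = 0.741), did not pass either.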

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

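The tests of list medians against random lists, of transcripts shared by probe sets, of RNA 5′ ends, of the whole cell cycle, of the genes around KCP and of its signal level were chosen only after the results were seen. The counts over other splits of the arrays were planned.

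The 650 genes and 1141 probe sets that passed came from 1 of the 10 ways to split the 6 arrays into 3 and 3, and the highest count in any other split was 0 genes and 0 probe sets. The labelled split also gave the most gene lists, 6 against at most 3 in another, so 1 of 10 splits reached each of these results. With 10 splits no share under 0.05 can be reached.

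Probe sets outside the comparison by gene also changed. Among the 1832 probe sets with several gene symbols, 52 passed the threshold, 30 higher and 22 lower. Among the 2473 that the annotation does not list, 59 passed, 21 higher and 38 lower. Of the arrays' 102 control probe sets, 2 passed when adjusted among the controls alone, the actin 5′ probe set (−0.36, adjusted p = 0.0189) and 1 for a human transcript (0.28, adjusted p = 0.0272). Among those that did not pass, 23 of 24 labelling spike-in probe sets (median 0.15) and 18 of 18 hybridisation spike-in probe sets (median 0.082) were higher in the knockout arrays.

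Mitotic genes and hypoxia and glycolysis genes were lower in the knockout arrays. Their medians, −0.22 and −0.25, lay outside the central 95% of 10000 random lists of equal size matched on mean signal (−0.051 to 0.061 and −0.059 to 0.073), which argues against a trend with signal brightness. The G1/S and replication list had a median of −0.018, so its genes did not fall as much as the mitotic ones. Its SD of 0.14 over members is a spread between genes, not an error of the median. Of 61 genes of the canonical histone families, 9 fell and 0 rose (median −0.14). They were picked by family name after their values were seen, so they do not measure the share of cells in S phase. The G1/S list alone does not settle whether a smaller share of cells was in the whole cycle, which stays open. A loss of RNA 5′ ends cannot be told apart from the grouping, since the actin and GAPDH controls disagree. The actin 5′ minus 3′ difference fell by 0.19 (exact p = 0.1, the smallest possible) and that of GAPDH was 0.013 (exact p = 0.7). The HUMISGF3A control went in the direction of actin, rising less at its 5′ (0.079) than at its 3′ probe set (0.28). M27830 (0.22 and 0.022) and HUMRGE (0.18 and 0.20) are not read as signs of messenger RNA integrity. Such a loss stays open beside an effect of KCP loss, a difference between clones, unequal drug exposure or culture density. None of these other causes was tested.

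Interferon-stimulated genes were higher, with a median of 0.19 against −0.042 to 0.059 for the central 95% of matched random lists, which argues against a trend with signal brightness. Without probe sets that can bind several transcripts the median was 0.21, which argues against such cross-binding as the source. The guide RNAs were delivered by virus, and a difference in viral dose or in the cells' response to DNA cutting may raise these genes, as may loss of KCP itself. No sample in the comparison separates these, and none was tested.

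The KCP signal did not differ detectably, and the median of its neighbours was negative, although 0 of 10 passed and the list lost its call with an estimated correlation (adjusted p = 0.315). The brighter KCP probe set lies at percentile 43.3 of all probe sets, and without detection calls it stays open whether it was above background. The 5 measured genes on each side of KCP had a median of −0.13, at percentile 0.565 of 17865 such windows over the genome and 4.88 of the 819 on chromosome 7, but 9 of them belong to the neighbour list, so this restates the list and does not test a local change. Such a change, a shift of the whole chromosome and a difference between the cell populations unrelated to cutting cannot be told apart around KCP, and DNA was not analysed here.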

How the results depend on the processing

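Leaving out probe sets that can bind several transcripts and using the other KCP probe set were chosen after the data were seen; the other alternatives were planned. The hypoxia, mitosis and interferon lists kept their direction and their call in all 18 alternatives (medians −0.29 to −0.23, −0.24 to −0.19 and 0.16 to 0.23). The number of genes past the threshold was 1617 without the dimmest 40% of probe sets, 2036 with an intensity trend and robust moderation and 1097 with array weights, against 650; 624, 640 and 649 of the 650 were among them. Probe sets numbered 3436 without the dimmest 40%, 1730 without the dimmest 20%, 4412 with the trend and 1859 with array weights, against 1141, and 638 without those that can bind several transcripts, fewer being tested. At least 1.5-fold were 45 genes and 111 probe sets, at least 2-fold 7 and 17, and with an unadjusted p and 1.5-fold 48 and 120. With fewer arrays, leaving out 1 gave 65 to 537 genes and 60 to 691 probe sets, and 4 to 27 of the 49 named genes past the threshold lost it (4 without control replicate 3, 27 without knockout replicate 2). With the replicate number as a block, 228 genes (220 of them shared with the 650) and 94 probe sets passed, and 18 of the 49 named genes did not, CCND1 among them (adjusted p = 0.0577). Deviations of same-numbered arrays correlated at 0.20, 0.046 and 0.19, and those of differently numbered arrays at −0.25 to 0.084. The same-numbered values were not all above 0.1. Control replicate 2 correlated more with knockout replicate 1 (0.084) than with its own number. The numbers were therefore not taken to pair the arrays in the main fit. A pairing is not excluded, and with it the lower counts of the block would apply. KCP never passed; its difference turned positive with the mean of its probe sets (0.039) and with the other probe set (0.10), and ranged from −0.15 to 0.054 with 1 array left out, where SPI1 ranged from −0.075 to 0.0021. PML turned positive with the mean of its probe sets (0.095), with the most variable one (0.46, adjusted p = 0.0221, adjusted p 0.0221 to 0.949 over its alternatives) and without those that can bind several transcripts (0.21); without these, ABCC3 was −0.15 and the ribosomal median −0.012. The turns of PML, ABCC3 and the ribosomal list, and those of KCP with other probe sets, follow from the probe sets used. Those with 1 array left out depended on which array it was: KCP was −0.15 without control replicate 3 and 0.050 without control replicate 2. The number of lists past the threshold was 6, and 3 with an estimated correlation, 10 with fry in a single direction and 25 with fry in either direction, which tests a different question. In a single direction fry added apoptosis promoters (adjusted p = 0.0255), apoptosis inhibitors (0.0052), TGF-beta (0.00162) and the unfolded protein response (0.011). With camera, calls were gained by BMP (−0.072) and TGF-beta (−0.075) without the dimmest 40%, and by apoptosis inhibitors with the most variable probe set (−0.17) or without those that can bind several transcripts (−0.12). The KCP neighbours passed in 10 of 18 alternatives (adjusted p 0.0138 to 0.315). For results other than these the cause was not tested. Over all alternatives, named genes lost a call 155 times and gained a call 26 times. Leaving aside fry in either direction, 16 of the 27 lists passed in none. Without detection calls, changes of dim probe sets cannot be separated from background.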

Other observations

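All tests in this part were chosen only after the values were seen. The histone and aryl hydrocarbon receptor genes were picked because members of them stood among the larger changes, so no test of whether either group moved as a whole is given. The random lists of like signal bear only on a trend with brightness.

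Several canonical histone genes were lower in the knockout arrays. Of 61 measured members of the canonical histone families, 9 fell and 0 rose, 52 differences were negative and the median was −0.14. Random lists of genes of like signal had medians of −0.042 to 0.032 (central 95%), so genes of that brightness showed no shift of this size. H3C4 (1.55-fold), H2AC6 (1.49-fold) and H2BC11 (1.48-fold) fell most. Members are close in sequence and are not separate measurements, and with the 34 whose probe sets are not of a kind that binds several transcripts the median was −0.12.

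A pair of target genes of the aryl hydrocarbon receptor, a sensor of planar aromatic compounds, were higher. CYP1A1, its classical target, rose 1.68-fold and its repressor AHRR 1.56-fold, while the other 5 of 7 measured targets did not pass: ALDH3A1 at 0.24, TIPARP at 0.22, CYP1B1 at 0.14, NQO1 at 0.11 and CYP1A2 at −0.011. The median of the 7 was 0.22, and random lists of genes of like signal had medians of −0.094 to 0.11. Further genes at least 1.5-fold higher included TCN1, a cobalamin carrier gene (1.70-fold), PRPH, a neuronal intermediate filament gene (1.69-fold), the EGF receptor ligand gene BTC (1.55-fold) and CD83 (1.52-fold), and those lower included PTGS1, a cyclooxygenase gene (1.55-fold), and SLC1A3, a glutamate transporter gene (log2 difference −0.59).

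Genes of chromosome 7, which carries KCP, were lower as a group. The median of its 829 measured genes was −0.046, the lowest of 23 chromosomes, with 64.2% of differences negative, 25 genes lower and 6 higher past the threshold. Elsewhere 211 were lower and 408 higher (Fisher's exact p = 2.97e-07 across genes, which are not independent). Relative to all genes, the chromosome stood at 0.024 ± 0.0028 in control and −0.023 ± 0.0041 in knockout arrays (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest possible). A trend with signal brightness is argued against, since the median lay outside the central 95% of matched random lists (−0.010 to 0.0088). Chromosomes 19 and 22 (low) and 3, 10, 15 and 16 (high) lay outside their own such ranges by less, with medians from −0.014 to 0.016. The random lists draw genes one by one, here and for the gene lists. Their ranges leave out shifts that genes share on an array and may be too narrow. If a break at KCP had removed the rest of the arm in some cells, genes beyond it would be lower than genes before it. The median of the 200 genes beyond KCP was −0.080 and that of the 200 before it −0.044, a difference of −0.036. Shuffling genes between the sides gave a two-sided permutation p of 0.0452. That p was 0.325 against the 50 genes before KCP, 0.19 against 100 and 0.00126 against 300. These p-values run across genes, which are not independent, and not across arrays. The nearest 40 genes before KCP had a median of −0.066 and the nearest 40 beyond it −0.12, against −0.033 for the 428 genes of the chromosome outside the 200 on either side. Whether a change starts at KCP therefore stays open, and a copy-number difference of the whole chromosome between the cell populations may give the same values.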
